A study of Arabidopsis thaliana and Arabidopsis lyrata and Capsella rubella with 303 samples.

How the data were processed

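Total RNA of dissected organs of A. thaliana (Col-0), A. lyrata (MN47), C. rubella, E. salsugineum, T. hassleriana, M. truncatula and B. distachyon was measured by strand-specific sequencing. Per the labels' protocols, plants grew on soil, apart from those for early root samples, which grew on agar plates. RNA was isolated on columns, and spike-in RNA (ERCC) was added before ribosomal RNA depletion and paired-end sequencing. Per the submitters' processing notes the authors used cutadapt 1.10, STAR 2.7.1a and Salmon 0.14.1; their roles and the genome build are not given in the sources used here. The deposited values are expected counts per gene, estimated by the authors from the reads and not scaled between libraries; 84.1 to 96.8% of the values above 0 in a library were whole numbers, and all were rounded. The deposited annotation, assembled by the authors, gives the start and end of genes, of transcripts they added and of LTR retrotransposons. Symbols came from the RefSeq table of assembly TAIR10.1, matched by locus: of 27546 nuclear protein-coding A. thaliana genes 27408 were in that table, all overlapping and 14718 with the same start and end. Coordinates are those of the deposited annotation.

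Spike-in counts were left out of the totals and held 0.63 to 2.21% of a library. Median gene counts per library ran from 32.93 M in C. rubella to 40.28 M in T. hassleriana. Reads are not independent molecules, so intervals and floors cover counting error only. Replicate pairs varied more than counting error alone gives, with a lowest chi-square per degree of freedom of 1.57. Groups follow the labels, which give no batch, lane or date. The replicate numbers were not taken as pairs.

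Genes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM scaling, filterByExpr) and called at a Benjamini-Hochberg adjusted p below 0.05. SE is the absolute log2 fold change divided by the square root of F. The root, apex, clv1, senescence, seed and A. lyrata stamen comparisons used the 6 libraries of both groups. Floral organs were fitted together in 12 libraries. Pollen was fitted with 27 libraries of 9 matched organs per species and compared with the mean on the log scale of 6 of them, without stamen and flower, which hold pollen. In M. truncatula and B. distachyon the labels name other tissues or stages for some of the matched organs, such as mesocotyl for hypocotyl and spikelet meristem for inflorescence apex in B. distachyon. CPM in the comparisons are on TMM-scaled totals, which differ several-fold from library totals in pollen, while CPM in the plots of single genes, per library and over the 44 A. thaliana groups are on library totals. A fold against 0 counts is a bound from a floor of 3 counts over the group. With 1 to 3 counts the ratio is given with its 95% counting interval (exact binomial), since a fitted fold change there depends on the prior count. For genes low in 1 organ against several, the counts and the CPM of other organs are given instead, as pooled counts may rest on 1 organ.

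From textbook knowledge 27 gene lists with 380 entries were written before the data were examined, as were the groups, the tests, most alternatives and the rule for named genes. The tables paired 372 entries with the symbol used, and 8 are named otherwise. The results name each list. Each was tested in its comparisons by camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the lists of a comparison, and also with an estimated correlation. Members passing are counted among all genes tested and adjusted over the list alone.

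Named genes are the 3 highest and 3 lowest called protein-coding genes that have a symbol, a mean of at least 10 CPM and no overlap between the libraries compared. From each list the rule adds up to 3 called members with the largest absolute change and a mean of at least 1 CPM, or its most abundant member where none is called. Highest, lowest and largest refer to genes open to this rule. CLV1, WUS, CLV3, PLT1, PLT2, LFY, AP1, FT, SAG12, AP3, PI, AG and VGD1 are always named in their comparisons. In the other species 1 highest and 1 lowest gene are named by identifier.

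Across species, genes at a mean of at least 1 CPM, the share of counts in the 100 most abundant genes, Spearman correlations of organ means and tau on log2(CPM + 1) over 8 organs were compared by two-sided exact sign-flip permutation over 7 species, with 128 sign patterns and 5 tests in the family. Non-coding genes exclude rRNA, tRNA, transposons and pseudogenes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for these and the plots.

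Alternatives were RLE size factors, no low-count filter, the DESeq2 1.42.0 Wald test, replicate number as a block, leaving out each library, an absolute log2 fold change of at least 1, nuclear protein-coding genes only, all libraries of the species or only the 7 organs in the fit, leaving out each reference organ, and, across species, other thresholds, thinning, pseudocounts, organs and species left out and matching on level. Library totals or spike-in counts as the scale, the 28 d apex as reference and leaving the 100 most abundant genes out of the totals were added after the data were seen. The procedure was tested on simulated data with 200 changed genes in each of 17 comparisons: 32.8 to 88.1% of genes changed 1.5-fold, 67.2 to 100.0% of those changed 2-fold and 89.4 to 100.0% of those changed 4-fold were called, and 1.55 to 10.2% of calls were false.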

Results

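Total RNA was sequenced from organs of 7 flowering plants in 303 libraries that fall into 101 groups of organ, age and stage, each with 3 replicates. Arabidopsis thaliana gave 44 groups and 132 libraries, Arabidopsis lyrata 12 groups and 36 libraries, and Capsella rubella, Eutrema salsugineum, Tarenaya hassleriana, Medicago truncatula and Brachypodium distachyon 9 groups and 27 libraries each. The A. thaliana groups run from seedling roots, leaves and shoot apices through dissected floral organs and mature pollen to siliques and seeds. The libraries held 8.02 to 74.05 M gene counts. The 3 below 20 M were the B. distachyon pollen libraries. Replicates of a group had a median Spearman correlation of 0.996 across genes, and the lowest pair, at 0.9469, was replicates 2 and 3 of the A. thaliana stage 15 stamens. Fold changes are given on the log2 scale with their standard error, levels as CPM on TMM-scaled totals with the SD, and n = 3 libraries per group throughout. Each adjusted p-value measures an effect against the spread between these libraries.

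In 5 d A. thaliana roots, regulators of the root stem cells and root cap and genes of DNA replication were higher in the root tip, and genes of suberin, xylem, root hairs and ion uptake were higher in the maturation zone. PLT1 (AT3G20840, chromosome 3, 7300231 to 7303734), a regulator of the root stem cell niche, rose by 5.06 ± 0.33 in the tip, and PLT2 (AT1G51190), at 19.4 ± 0.449 CPM there, by 5.06 ± 0.30. CYP86A1 (AT5G58860, chromosome 5, 23765791 to 23768111), a hydroxylase of suberin synthesis, stood at 1.09 ± 0.172 CPM in the tip and 336 ± 27.5 CPM in the maturation zone, a log2 fold change of -8.26 ± 0.12. The comparison asks how the dividing tip of the root differs from its differentiated part.

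Of the 13 measured genes of the root stem cell niche and root cap list, 12 rose and 1 fell in the tip (median 5.06; camera adjusted p = 0.00865, adjusted p = 0.367 with an estimated correlation). FEZ (AT1G26870, 5.99 ± 0.48), BRN2 (AT4G10350, 5.51 ± 0.38) and BRN1 (AT1G33280, 5.46 ± 0.41), transcription factors of root cap development, rose most. This list summed to 104, 88.8 and 90.7 CPM of the library totals in the 3 maturation zone libraries. Without replicate 1 of these, FEZ rose by 10.18, BRN2 by 7.52, BRN1 by 7.12 and PLT1 and PLT2 by 6.08 each. Every one of the 21 cell division and DNA replication genes rose (median 1.65; camera adjusted p = 4.51e-07, adjusted p = 0.258 with an estimated correlation), among them the replication licensing genes CDT1A (AT2G31270, 3.02 ± 0.12) and CDC6 (AT2G29680, 2.36 ± 0.11) and the mitotic cyclin CYCB1;1 (AT4G37490, 2.28 ± 0.09). All 14 endodermal barrier genes fell (median -5.36; camera adjusted p = 4.88e-14, adjusted p = 0.0557 with an estimated correlation), KCS2 (AT1G04220) by 7.63 and GPAT5 (AT3G11430) by 7.62. So did the 14 measured genes of xylem and the secondary wall (median -4.28; camera adjusted p = 6.43e-12, adjusted p = 0.0557 with an estimated correlation), with the vessel regulator VND6 (AT5G62380) at -6.63 ± 0.33 and the lignin laccases LAC17 (AT5G60020) at -6.18 ± 0.13 and LAC4 (AT2G38080) at -5.49 ± 0.13. Root hair genes gave 10 lower and 3 higher of 13 (median -3.45; camera adjusted p = 0.000767, adjusted p = 0.266 with an estimated correlation), led by the wall proteins PRP3 (AT3G62680, -4.98 ± 0.23) and LRX1 (AT1G12040, -4.59 ± 0.20) and by RHS19 (AT5G67400, -4.52 ± 0.12). Of 12 ion uptake genes 11 fell (median -2.09; camera adjusted p = 0.0104, adjusted p = 0.266 with an estimated correlation), including the iron transporter IRT1 (AT4G19690, -7.09 ± 0.34), the phosphate transporter PHT1;1 (AT5G43350, -3.95 ± 0.11) and the sodium transporter HKT1 (AT4G10310, -3.28 ± 0.25).

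Photosynthesis genes were low in both parts, and 15 of 20 fell in the tip while 5 did not pass (median -2.42; camera adjusted p = 0.00865, adjusted p = 0.472 with an estimated correlation); LHCA3 (AT1G61520) went from 31.3 ± 2.58 CPM in the maturation zone to 1.24 ± 0.591 CPM in the tip, with PSAD-1 (AT4G02770) at -4.11 ± 0.14 and PSBO1 (AT5G66570) at -4.00 ± 0.14. The jasmonate and wounding list had 9 lower, 1 higher and 2 not passing and was not called as a list (camera adjusted p = 0.0767, or 0.0202 with spike-in counts); ZAT10 (AT1G27730) fell by 3.80, JAZ5 (AT1G17380) by 3.71 and VSP1 (AT5G24780) by 3.62. Outside the lists, the largest rises were those of the prenyltransferase gene CPT (AT2G23410, 5.84 ± 0.41) and of the paralogous myrosinase genes BGLU35 (AT1G51470, 5.76 ± 0.98) and BGLU34 (AT1G47600, 5.71 ± 1.02), whose values may share reads and whose maturation zone level ran from 0.762 to 22.8 CPM for BGLU35; without maturation zone replicate 1 BGLU34 lay at 8.70. The largest falls were those of PDLP4 (AT3G04370, -8.69 ± 0.11), a plasmodesmal protein gene, NAC100 (AT5G61430, -8.63 ± 0.18) and CYP79F2 (AT1G16400, -8.53 ± 0.12), which acts in glucosinolate synthesis. Of 21925 genes tested by edgeR, 19709 were called, 10026 higher and 9683 lower in the tip, and 12332 had an absolute log2 fold change of at least 1. In this comparison each list kept its counts when adjusted over the list alone, and with spike-in counts as the scale the median of all genes moved from 0.038 to 0.39.

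At the transition from the vegetative apex (14 d) to the inflorescence apex (21 d) of A. thaliana, the floral identity genes AP1 and LFY rose and FLC and SNZ, repressors of flowering, fell. AP1 (AT1G69120, chromosome 1, 25982294 to 25986349) went from 3.80 ± 0.372 to 188 ± 5.24 CPM (5.61 ± 0.05), and LFY (AT5G61850) from 3.22 ± 0.0754 to 59.2 ± 2.52 CPM (4.21 ± 0.06). FLC (AT5G10140, chromosome 5, 3173382 to 3179727) fell from 19.3 ± 1.72 to 0.0773 ± 0.0949 CPM (-7.63 ± 0.22, or -9.27 without inflorescence replicate 1), and SNZ (AT2G39250) by 6.36. FT (AT1G65480), which is expressed in leaves and acts in the apex, was below the low-count filter with 0 counts over the 3 inflorescence libraries and 1 over the 3 vegetative ones. The comparison asks which genes distinguish a flowering from a leaf-forming shoot tip.

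The flowering time and floral identity list, which holds activators and repressors, had 12 of 19 measured genes higher and 7 lower (median 1.87; camera adjusted p = 9.05e-12, and adjusted p = 0.0453 with an estimated correlation). Of the 9 floral homeotic genes 8 rose and 1 fell (median 5.45; camera adjusted p = 2.4e-32, and adjusted p = 0.0453 with an estimated correlation), with SEP2 (AT3G02310) at 5.70 ± 0.13 and AP3 (AT3G54340) at 5.66 ± 0.10. Shoot meristem genes gave 20 higher, 1 lower and 1 not passing of 22 (mean 1.12; camera adjusted p = 1.62e-12, adjusted p = 0.194 with an estimated correlation). The stem cell regulators WUS (AT2G17950) and CLV3 (AT2G27250) rose by 2.91 ± 0.13 and 2.08 ± 0.20, and the boundary gene CUC1 (AT3G15170) by 2.28 ± 0.06. Cell division genes moved by less: 20 of 21 rose and 1 fell (median 0.40; camera adjusted p = 0.000112, adjusted p = 0.231 with an estimated correlation), as for CYCB1;1 at 0.67 ± 0.03, CDKB2;1 (AT1G76540) at 0.62 ± 0.03 and CDKB2;2 (AT1G20930) at 0.55 ± 0.05.

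All 20 photosynthesis genes fell (median -0.93; camera adjusted p = 5.19e-11, adjusted p = 0.196 with an estimated correlation), among them LHCB2.1 (AT2G05100), from 248 ± 8.70 to 68.6 ± 5.26 CPM, RBCS2B (AT5G38420, -3.79 ± 0.14) and RBCS1B (AT5G38430, -2.15 ± 0.11). The other 3 lists were not called. Carpel and ovule genes had 3 higher and 8 lower of 11 (median -1.21, mean -0.927, while the test ranked the list upward; camera adjusted p = 0.643). CRC (AT1G69180) and NGA3 (AT1G01030) fell by 3.98 and 3.13 and SPT (AT4G36930) rose by 2.01 ± 0.05. Of the jasmonate and wounding genes 5 were higher, 8 lower and 1 not passing (median -0.65, mean -0.55, with the test upward; camera adjusted p = 0.88): the vegetative storage protein genes VSP1 (1570 ± 133 against 81.9 ± 1.28 CPM) and VSP2 (AT5G24770, 3.20 ± 0.07) rose and AOC1 (AT3G25760), of jasmonate synthesis, fell by 4.54. Of 4 measured heat shock genes 3 rose, HSP70 (AT3G12580) by 1.09 ± 0.17, HSP18.2 (AT5G59720) by 0.95 ± 0.12 and HSP90.1 (AT5G52640) by 0.39 ± 0.13 (camera adjusted p = 0.481). The call of HSP90.1 was lost without inflorescence replicate 1 or 3 (adjusted p = 0.0809 and 0.0536) with DESeq2 (0.0689) and with all A. thaliana libraries in the fit (0.0788). The largest rises were those of the sugar transporter SWEET10 (AT5G50790, 9.35 ± 0.22), the wax hydroxylase CYP96A15 (AT1G57750, 8.23 ± 0.11) and the MADS-box gene AGL44 (AT2G14210, 7.89 ± 0.11). The peroxidase gene PER70 (AT5G64110) and PDF1.5 (AT1G55010) had 0 counts in the inflorescence apex and were at least 4800-fold and at least 877-fold lower, and P4H8 (AT4G35810), with 1 count, was 6380 times lower (counting interval 1150 to 252000).

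Of 21719 genes tested, 15934 were called, 7844 higher and 8090 lower, and 4515 changed by at least 1 on the log2 scale, 1436 upward and 3079 downward. The counts of all 8 lists were the same when adjusted over the list alone. With spike-in counts as the scale the split became 10417 higher and 4381 lower and the median of all genes lay at 0.25, against 0.0038.

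In the inflorescence apex labelled clv1, the stem cell genes CLV3 and WUS were higher and the cell division genes lower than in the unlabelled apex of 21 d. CLV3 (chromosome 2, 11664978 to 11665797), the peptide ligand of the CLAVATA pathway, stood at 357 ± 33.5 CPM against 2.53 ± 0.295 CPM (7.13 ± 0.10). WUS (chromosome 2, 7808871 to 7810811), the transcription factor that this pathway restrains, stood at 33.8 ± 2.91 against 6.93 ± 0.210 CPM (2.29 ± 0.07). The transcript of CLV1 itself (AT1G75820), the receptor kinase gene after which the libraries are labelled, was at 191 ± 8.48 against 115 ± 0.506 CPM (0.73 ± 0.04). All 21 cell division and DNA replication genes fell (median -0.97; camera adjusted p = 3.16e-16, adjusted p = 0.247 with an estimated correlation), PCNA1 (AT1G07370) by 1.19, CYCB2;2 (AT4G35620) by 1.18 and AUR2 (AT2G25880) by 1.17. The comparison asks how the apex labelled clv1 differs from the unlabelled one; the labels give neither the allele nor the exact age of these plants, which are marked 21d+.

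The shoot meristem list as a whole moved both ways, with 10 higher, 9 lower and 3 not passing of 22, CLV3, WUS and CLV1 included (median 0.05; camera adjusted p = 0.248, but 0.000527 against the 28 d apex). CUC3 (AT1G76420) lay at -1.49 ± 0.06. Of the 12 measured carpel and ovule genes 10 rose, 1 fell and 1 did not pass (median 1.89; camera adjusted p = 0.000113, adjusted p = 0.247 with an estimated correlation). SHP1 (AT3G58780) rose by 3.90 ± 0.24, and CRC by 5.05 ± 0.28 and NGA3 by 3.06 ± 0.24, but against the 28 d apex CRC lay at -0.12 and NGA3 at -0.23. Flowering time and floral identity genes split into 7 higher, 5 lower and 5 not passing (median 0.08; camera adjusted p = 0.809, but 0.0204 against the 28 d apex). TOE1 (AT2G28550) lay at 1.46 ± 0.09, SVP (AT2G22540) at 1.09 ± 0.04 and SPL9 (AT2G42200) at -1.29 ± 0.06. The 9 floral homeotic genes had 4 higher and 5 lower (median -0.16; camera adjusted p = 0.816, but 0.00143 against the 28 d apex); AP2 (AT4G36920) and AP1 fell by 0.77 and 0.75, and SEP3 (AT1G24260) rose by 0.65 ± 0.08 here and fell by 0.78 against the 28 d apex. Photosynthesis genes had 9 higher, 5 lower and 6 not passing (median 0.13; camera adjusted p = 0.354). LHCA4 (AT3G47470) lay at 0.77 ± 0.06, LHCA2 (AT3G61470) at 0.69 ± 0.05 and LHCB2.1 at 0.55 ± 0.05, or -0.14 against the 28 d apex. Jasmonate and wounding genes had 6 higher, 3 lower and 4 not passing (median -0.18, mean 0.63, with the test downward; camera adjusted p = 0.838), and ZAT10 (4.02 ± 0.56), JAZ7 (AT2G34600, 3.74 ± 0.49) and WRKY40 (AT1G80840, 2.92 ± 0.58) rose; ZAT10 and WRKY40 lay at 3.21 and 1.97 without clv1 replicate 3, and JAZ7 at 4.75 without 21 d replicate 1. Of 4 heat shock genes HSP101 (AT1G74310) alone passed, at 0.40 ± 0.07 (camera adjusted p = 0.828).

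The largest rise was that of ASN1 (AT3G47340, chromosome 3, 17437840 to 17441431), an asparagine synthetase gene induced by darkness and low sugar, at 470 ± 75.4 against 1.72 ± 0.420 CPM (8.13 ± 0.18), followed by QQS (AT3G30720, 7.77 ± 0.07) and the drought-induced linker histone gene HIS1-3 (AT2G18050, 7.34 ± 0.75). The largest falls were those of DIR13 (AT4G11190, -5.40 ± 0.06), the laccase gene LAC1 (AT1G18140, -4.57 ± 0.12) and the beta-amylase gene BAM5 (AT4G15210, -4.21 ± 0.58, or -5.53 without clv1 replicate 3). Of 21418 genes tested 15235 were called, 7657 higher and 7578 lower, and 3366 changed by at least 1, 2277 upward and 1089 downward. With spike-in counts as the scale the split was 7863 higher and 3970 lower and the median of all genes 0.15, and the list counts did not alter when adjusted over the list alone.

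**Figure D1:**
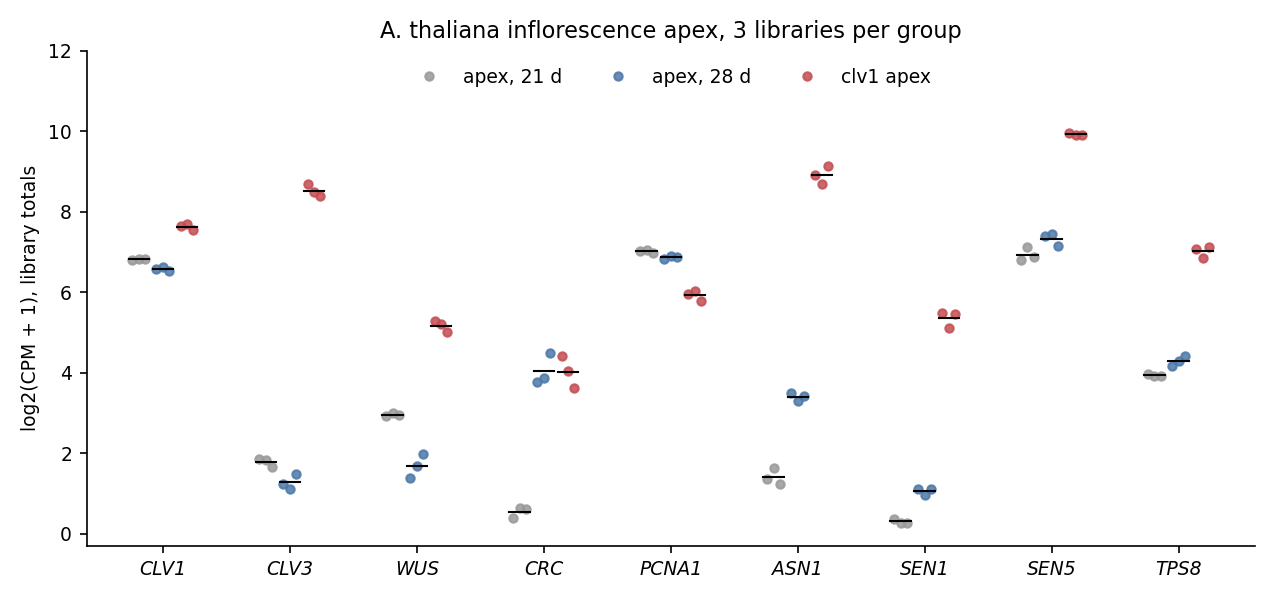
Levels of 9 genes in the 3 libraries of the 21 d inflorescence apex, the 28 d inflorescence apex and the apex labelled clv1, as log2(CPM + 1) of the library totals; points are libraries and black lines are means. CLV3, WUS and ASN1 lie above both other apex groups in all 3 clv1 libraries, while CRC lies at about the level of the 28 d apex.

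In senescing leaves (35 d), regulators of senescence rose and genes of DNA replication and of salicylic acid defence fell relative to leaves 9 and 10 (27 d). ORE1 (AT5G39610, chromosome 5, 15858398 to 15859911), a transcription factor that promotes leaf senescence, rose from 8.04 ± 0.622 CPM by 4.13 ± 0.11, and its relative ORS1 (AT3G29035) stood at 125 ± 3.14 against 11.0 ± 2.12 CPM (3.50 ± 0.11). SAG12 (AT5G45890), a protease gene used as a senescence marker, rose by 3.94 ± 0.91, with 37.7 ± 23.5 against 2.53 ± 4.26 CPM (8.85 without leaf 9 and 10 replicate 3; adjusted p = 0.0508 with DESeq2). PCNA1, the replication clamp, fell from 11.6 ± 0.713 to 0.506 ± 0.153 CPM (-4.49 ± 0.18). The comparison asks how senescing leaves, labelled without leaf number, differ.

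Of 18 senescence and chlorophyll breakdown genes 14 rose, 2 fell and 2 did not pass (median 1.02; camera adjusted p = 4.12e-08, adjusted p = 0.141 with an estimated correlation). Autophagy genes had 7 of 11 higher, none lower and 4 not passing (median 0.46; camera adjusted p = 0.0139, adjusted p = 0.325 with an estimated correlation), ATG8B (AT4G04620) rising by 1.40 ± 0.09, ATG8E (AT2G45170) by 0.83 ± 0.07 and ATG18A (AT3G62770) by 0.77 ± 0.11. Salicylic acid defence genes had 12 of 13 lower and 1 not passing (median -1.87; camera adjusted p = 4.2e-10, adjusted p = 0.141 with an estimated correlation): PR5 (AT1G75040) fell from 1160 ± 126 CPM by 2.41 ± 0.18, and FMO1 (AT1G19250) and ALD1 (AT2G13810), of pipecolate synthesis, fell by 2.94 and 2.67. Cell division genes had 19 of 20 lower (median -2.05; camera adjusted p = 4.2e-10, and adjusted p = 0.0162 with an estimated correlation), with the replication helicase genes MCM7 (AT4G02060) at -3.57 ± 0.15 and MCM3 (AT5G46280) at -3.26 ± 0.13.

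Photosynthesis genes had 17 of 20 lower and 3 not passing (median -0.52, but 0.09 with spike-in counts as the scale; camera adjusted p = 0.00921, adjusted p = 0.673 with an estimated correlation and 0.139 with spike-in counts). The small subunit genes of Rubisco, close paralogs that may share reads, fell by 0.88 (RBCS3B, AT5G38410), 0.86 (RBCS1B) and 0.80 (RBCS2B, but not called with spike-in counts, at -0.20 and adjusted p = 0.126). Cytosolic ribosome genes had 10 of 12 lower (median -0.41, but 0.20 with spike-in counts; camera adjusted p = 0.00436, adjusted p = 0.497 with an estimated correlation and 0.198 with spike-in counts), RPL28A (AT2G19730) at -0.95 ± 0.07, RPS6A (AT4G31700) at -0.86 ± 0.06 and PFL (AT1G22780) at -0.81 ± 0.06. Jasmonate and wounding genes had 5 higher, 6 lower and 3 not passing (median 0.02, mean -0.246; camera adjusted p = 0.377, or 0.0467 without senescing leaf replicate 2). ZAT10 rose by 2.54 ± 0.14 and VSP1 and VSP2 fell by 4.83 and 2.43. Heat shock genes had 1 higher, HSP70 (0.87 ± 0.16), and 4 lower of 6 (camera adjusted p = 0.395), among them HSP90.1 (-0.79 ± 0.07) and HSP101 (-0.46 ± 0.13), which with spike-in counts lay at -0.17 (adjusted p = 0.147) and 0.16 (adjusted p = 0.296). The largest rises were those of AGL42 (AT5G62165, 6.77 ± 0.17), PEPC1 (AT1G17710, 6.05 ± 0.45, or 7.35 without leaf 9 and 10 replicate 2) and MRD1 (AT1G53480, 5.13 ± 0.14). GILT (AT4G12960) had 0 counts in the senescing leaves and was at least 2140-fold lower, and LTP6 (AT3G08770) and FLA2 (AT4G12730) fell by 7.37 (9.45 without senescing leaf replicate 1) and 5.22. Of 1430 non-coding genes tested 864 rose and 141 fell, and of 135 LTR retrotransposon genes 83 rose and 9 fell, against 6482 higher and 7340 lower of 19581 protein-coding genes.

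Over all 21146 genes tested 14919 were called, 7429 higher and 7490 lower, and 5302 changed by at least 1. With spike-in counts as the scale the split was 14203 higher and 2708 lower with a median of all genes at 0.62 (0.11 with library totals, 0.011 with TMM), and each list had the same counts when adjusted over the list alone.

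Among the A. thaliana floral organs at stage 12, the class B and C homeotic genes separated the organs. AP1 stood at 376 ± 14.6 CPM in sepals and 179 ± 2.00 CPM in petals, against 0.981 ± 0.225 CPM in stamens. PI (AT5G20240, chromosome 5, 6828904 to 6831515) stood at 520 ± 5.26 CPM in petals and 437 ± 18.0 in stamens, against 2.84 ± 1.24 in sepals and 1.02 ± 0.540 in carpels. AP3 followed with 353 ± 9.28 CPM in petals, 256 ± 14.4 in stamens, 58.8 ± 4.97 in sepals and 6.37 ± 0.661 in carpels. AG (AT4G18960, chromosome 4, 10382856 to 10388539) stood at 190 ± 17.3 CPM in stamens and 101 ± 2.31 in carpels, against 0.471 ± 0.454 CPM in petals. The comparisons ask what is particular to each organ, and each sets 1 organ against the mean, on the log scale, of the other 3.

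**Figure D2:**
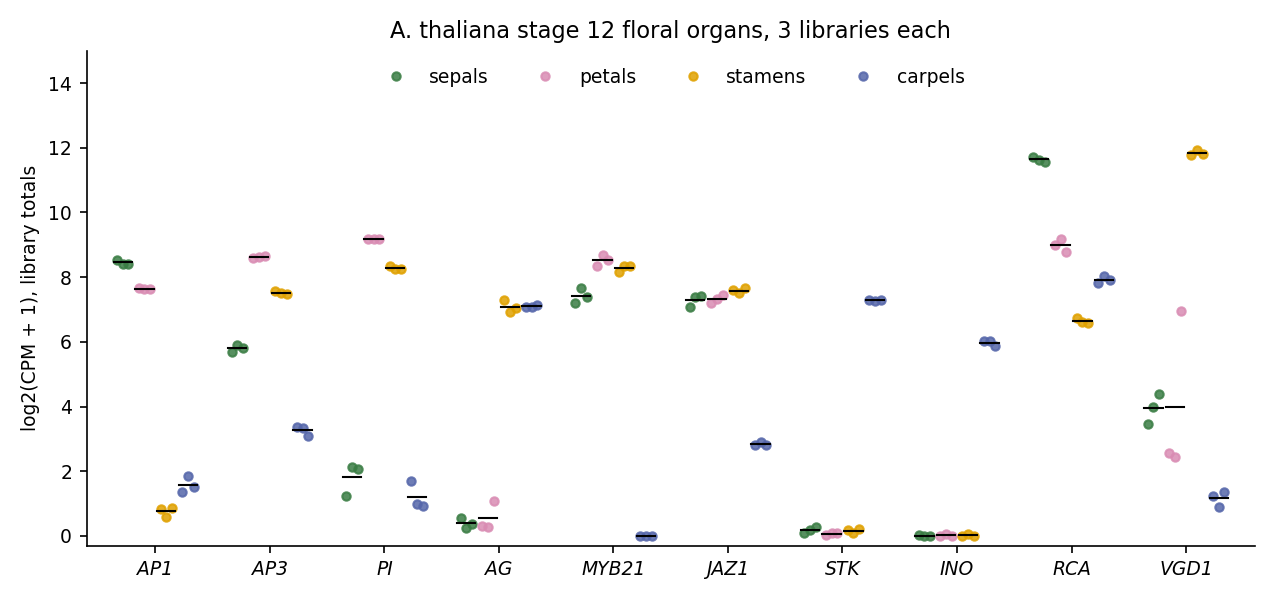
Levels of 10 genes in the 3 libraries each of stage 12 sepals, petals, stamens and carpels (the carpels labelled early stage 12), as log2(CPM + 1) of the library totals; points are libraries and black lines are means. AP1 is highest in sepals and petals, AP3 and PI in petals and stamens, and AG in stamens and carpels, and VGD1, a pollen gene, is higher in petal replicate 3 than in the other petal libraries.

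Stamens were marked by transcripts of pollen. All 23 pollen tube genes rose (median 10.22; camera adjusted p = 0.00784, adjusted p = 0.92 with an estimated correlation), among them CPK17 (AT5G12180, 315 ± 52.5 CPM, 11.10 ± 0.19), the profilin gene PRF5 (AT2G19770, 782 ± 76.2 CPM, 10.86 ± 0.91, or 12.65 without petal replicate 3) and the receptor kinase gene ANX2 (AT5G28680, 502 ± 80.8 CPM, 10.75 ± 0.27). All 10 sperm cell genes rose (median 8.67; camera adjusted p = 0.000139, adjusted p = 0.389 with an estimated correlation), such as PCR11 (AT1G68610) at 248 ± 34.6, the sperm histone MGH3 (AT1G19890) at 115 ± 7.78 and DAZ2 (AT4G35280) at 44.7 ± 4.27 CPM. Tapetum and exine genes had 8 higher and 6 lower of 14 (median 2.94; camera adjusted p = 0.6), the pollen coat genes GRP17 (AT5G07530, 9.32 ± 0.29) and GRP19 (AT5G07550, 8.34 ± 0.34) rising. All 20 photosynthesis genes fell (median -1.90; camera adjusted p = 1.47e-05, adjusted p = 0.558 with an estimated correlation), with PRK (AT1G32060) at 51.6 ± 1.95 CPM in stamens and 1550 ± 12.7 CPM in sepals, RBCS2B at -4.03 ± 0.44 and RBCS1B at -2.28 ± 0.15. Carpel and ovule genes had 2 higher, 11 lower and 4 not passing of 17 (median -1.34; camera adjusted p = 0.0337, adjusted p = 0.263 with an estimated correlation, 0.211 with library totals and 0.114 with spike-in counts); CRC was at 0.105 ± 0.0350 and HEC3 (AT5G09750) at 3.44 ± 0.732 CPM in stamens, against 10.5 ± 2.48 and 44.4 ± 3.48 in carpels, and HEC2 (AT3G50330), with 0 counts in stamens, at 15.3 ± 1.79 in carpels; its call was lost without sepal replicate 3 (adjusted p = 1.0).

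The floral homeotic list had 4 higher, 4 lower and 1 not passing in stamens (median 0.06, or -0.60 with library totals and -0.32 with spike-in counts; mean 0.356, with the test downward; camera adjusted p = 0.814). AG lay at 6.21 ± 0.15, PI at 5.25 ± 0.23, AP3 at 2.33 ± 0.06 and AP1 at -5.53 ± 0.16. Jasmonate and wounding genes had 8 higher, 3 lower and 3 not passing (median 0.48, or -0.17 with library totals; camera adjusted p = 0.814), the repressor genes JAZ1 (AT1G19180) and JAZ10 (AT5G13220) at 2.48 ± 0.07 and 1.69 ± 0.08 and WRKY40 at -2.71 ± 0.44. Flavonoid and floral volatile genes had 2 higher, 5 lower and 1 not passing (median -0.78, mean 0.779; camera adjusted p = 0.814). MYB111 (AT5G49330) fell by 1.43; the stamen regulators MYB21 (AT3G27810) and MYB24 (AT5G40350), at 437 ± 52.4 and 88.3 ± 16.5 CPM in stamens, had 0 and 2 counts in carpels. The highest of the called genes were EXPA24 (AT5G39310, 175 ± 23.4 CPM, 4 counts over the other 9 libraries), GPAT5 (955 ± 155 CPM, 13.21 ± 0.27), and MLO9 (AT1G42560, 82.9 ± 17.5 CPM, 9 counts over the other 9). ERF106 (AT5G07580) had 0 counts in stamens and 12.4 ± 0.377 CPM or more in the other organs, MO1 (AT4G15760) 2 counts in stamens and 50.6 ± 5.33 CPM in sepals, and IDD4 (AT2G02080) lay at -6.81 ± 0.23. Of 24042 genes tested 20823 were called, 10579 higher and 10244 lower, and 12211 changed by at least 1. The split was 7406 to 14200 with library totals (median of all genes -0.66, against -0.014) and 8441 to 12456 with spike-in counts (-0.39), and adjusted over the list alone the counts of the 8 lists were unaltered.

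Carpels were marked by ovule and gynoecium regulators. Of the 17 carpel and ovule genes 15 rose and 2 did not pass (median 5.58; camera adjusted p = 1.17e-15, and adjusted p = 0.00165 with an estimated correlation). The ovule identity gene STK (AT4G09960, chromosome 4, 6236375 to 6241281) stood at 115 ± 0.762 CPM against at most 0.166 ± 0.0614 in any other organ (10.03 ± 0.08). INO (AT1G23420), of the ovule integument, had 45.8 ± 2.50 CPM in carpels and 3 counts over the other 9 libraries, 4340 times higher than these pooled (counting interval 1490 to 21100), and HEC2 was 1450 times higher (495 to 7030). MYB21, AAE11 (AT1G66120) and MYB57 (AT3G01530) had 0 counts in carpels and at least 185 ± 32.1, 26.3 ± 13.7 and 23.2 ± 5.85 CPM in each other organ.

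Jasmonate and wounding genes had 11 lower, 1 higher and 2 not passing in carpels (median -1.47; camera adjusted p = 0.0401, adjusted p = 0.789 with an estimated correlation), JAZ1 at 4.58 ± 0.174 CPM against 143 ± 12.8 or more in the other organs, ZAT10 at -3.28 ± 0.59 (-5.26 without carpel replicate 2) and JAZ7 at -3.17 ± 0.19. Photosynthesis genes had 19 of 20 lower, and 20 adjusted over the list alone (median -0.70, but 0.17 with spike-in counts as the scale; camera adjusted p = 0.0401, adjusted p = 0.789 with an estimated correlation), RBCS1B falling by 2.39, RBCS2B by 1.94 and RBCS3B by 1.84. Both lists lost their call without carpel replicate 1 (camera adjusted p = 0.0579 each), carpel replicate 3 (0.0538) or stamen replicate 2 (0.0551) and with nuclear protein-coding genes only (0.055), and photosynthesis also without sepal replicate 1 (0.0585). All 23 pollen tube genes were lower (median -6.65), but the list was not called (camera adjusted p = 0.0653), though it was in 8 of its 20 alternatives (range 4.71e-05 to 0.789): without petal replicate 1, 2 or 3 (0.0234, 0.0251 and 0.00039), with all A. thaliana libraries in the fit (4.71e-05), library totals (0.00225), spike-in counts (0.000103) or no low-count filter (0.000355) among them. PPME1 (AT1G69940) had 0.141 ± 0.0548 CPM in carpels and 3520 ± 400 in stamens, PRF5 lay at -8.47 ± 1.72 and RALFL19 (AT2G33775) at -8.41 ± 1.18 (-6.66 and -7.41 without petal replicate 3). Sperm cell genes had 5 lower, 2 higher and 3 not passing (median -2.53; camera adjusted p = 0.772), PCR11, MGH3 and DAZ2 having 2, 2 and 1 counts in carpels and at most 0.476 ± 0.632 CPM in petals and sepals. MGH3 lost its call without sepal replicate 1 (adjusted p = 0.0742) and DAZ2 without petal replicate 3 (1.0). Tapetum and exine genes had 7 lower, 3 higher and 4 not passing (median -0.99; camera adjusted p = 0.583). QRT3 (AT4G20050) lay at -4.01 ± 0.20, MS2 (AT3G11980) at -3.63 ± 0.41 and EXL6 (AT1G75930) at -2.45 ± 0.37. Floral homeotic genes had 4 higher and 5 lower (median -0.48, but 0.10 with library totals and 0.39 with spike-in counts; camera adjusted p = 0.583). AG lay at 4.99 ± 0.16, PI at -6.40 ± 0.37, AP1 at -4.78 ± 0.15 and AP3 at -4.77 ± 0.09. Flavonoid and floral volatile genes had 4 higher and 3 lower of 8 (median 0.25, mean -3.09, with the test downward; camera adjusted p = 0.526). MYB12 (AT2G47460) rose by 1.39 ± 0.07. ADS1 (AT1G06080, 10.24 ± 0.11) and HB-3 (AT2G33880, 10.24 ± 0.10) followed INO among the genes open to the naming rule. Of the 24042 genes 20565 were called, 9997 higher and 10568 lower, and 11437 changed by at least 1. The split was 13738 to 6936 with library totals (median of all genes 0.46, against -0.12) and 15160 to 5451 with spike-in counts (0.75).

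Petals were marked by flavonoid and floral volatile genes, of which 7 of 8 rose and 1 fell (median 2.18; camera adjusted p = 1.04e-08, and adjusted p = 0.0178 with an estimated correlation). MYB111 (chromosome 5, 19998823 to 20001572), an activator of flavonol synthesis, stood at 44.7 ± 1.74 CPM against at most 8.76 ± 1.53 in any other organ (3.78 ± 0.09). MYB21 and MYB24 stood at 329 ± 38.4 and 65.4 ± 8.20 CPM, below their levels in stamens. Of the 9 floral homeotic genes 6 rose and 3 fell (median 0.83; camera adjusted p = 0.00375, adjusted p = 0.0784 with an estimated correlation and 0.0537 with no low-count filter), PI at 5.58 ± 0.23, AP1 at 4.44 ± 0.10, AP3 at 2.95 ± 0.06 and AG at -5.27 ± 0.41. The highest genes were UGT79B3 (AT4G27570, 6.70 ± 0.20), MEE26 (AT2G34870, 6.62 ± 0.16, or 8.07 without carpel replicate 2) and bbx23 (AT4G10240, 6.37 ± 0.11), and the lowest AO4 (AT1G04580, -7.59 ± 0.47), SWEET14 (AT4G25010, -7.09 ± 0.42, or -8.31 without petal replicate 1) and CYP705A24 (AT1G28430, -5.90 ± 0.77).

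Petal replicate 3 held the pollen tube list at 402 CPM of the library total, against 40.1 and 39.9 CPM in replicates 1 and 2, and the sperm cell list at 8.93 against 1.82 and 1.35 CPM. Pollen tube genes had 7 lower and 16 not passing, and 6 lower adjusted over the list alone (median -0.70; camera adjusted p = 0.27), but without petal replicate 3 the list was called (camera adjusted p = 1.08e-05), as in 5 others of its 20 alternatives (range 1.08e-05 to 0.896), among them all A. thaliana libraries in the fit (0.00781), library totals (0.0411), spike-in counts (0.015) and no low-count filter (0.0382); CNGC18 (AT5G14870) fell by 3.01, CPK17 by 2.78 and SPIK (AT2G25600) by 2.74. Without petal replicate 3, AO4 lay at -9.18, AG at -6.46, HEC3 at -6.20, GRP17 at -5.90, CNGC18 at -4.06, HAP2 at -3.62, CPK17 at -3.47 and GEX1 at -2.26. CPK17 lost its call without carpel replicate 3 (adjusted p = 0.976), and HEC3 without sepal replicate 1 (1.0). Sperm cell genes had 3 lower and 7 not passing (median -1.25; camera adjusted p = 0.301). GEX2 (AT5G49150) lay at -3.74 ± 0.16, HAP2 (AT4G11720) at -2.82 ± 0.72 and GEX1 (AT5G55490) at -1.57 ± 0.45. Tapetum and exine genes had 3 higher, 6 lower and 5 not passing (median -0.22, but 0.08 with spike-in counts; camera adjusted p = 0.411). GRP17, EXL6 and GRP19 fell by 5.26, 3.89 and 3.75. Carpel and ovule genes had 3 higher, 10 lower and 4 not passing (median -2.16; camera adjusted p = 0.301). HEC3 fell by 5.00 and STK by 4.90, and STY1 (AT3G51060) had 1 count, against 11.7 ± 1.30 CPM in carpels and at most 0.0642 ± 0.0376 in the other organs. Photosynthesis genes had 8 higher, 1 lower and 11 not passing (median 0.11; camera adjusted p = 0.847). LHCA2 stood at 337 ± 18.6 CPM (0.65 ± 0.05), LHCB4.1 (AT5G01530) at 0.41 ± 0.05 and LHCA1 (AT3G54890) at 0.40 ± 0.06. In the jasmonate and wounding list 3 were higher, 6 lower and 5 not passing (median -0.35, mean -0.745, with the test upward; camera adjusted p = 0.88). CORI3 (AT4G23600), ZAT10 and AOC1 fell by 4.44, 3.16 and 2.76. In petals 16892 genes were called, 8077 higher and 8815 lower, and 6517 changed by at least 1. The split was 10916 to 6521 with library totals (median of all genes 0.14, against -0.064) and 11703 to 5611 with spike-in counts (0.24).

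Sepals were marked by photosynthesis genes, of which all 20 rose (median 2.42; camera adjusted p = 4.37e-12, adjusted p = 0.512 with an estimated correlation). RCA (AT2G39730, chromosome 2, 16570746 to 16573779), the activase of Rubisco, stood at 3420 ± 151 CPM against 457 ± 61.1 in petals (3.93 ± 0.07), and RBCS2B and RBCS1B, which may share reads, rose by 5.97 ± 0.32 and 4.56 ± 0.12. No other list was called. The list of jasmonate and wounding had 10 higher, 2 lower and 2 not passing (median 1.80; camera adjusted p = 0.176). It was called in 6 of its 20 alternatives (range 0.00281 to 0.922), among them spike-in counts (0.0279), no low-count filter (0.0128), all A. thaliana libraries in the fit (0.0283), without sepal replicate 1 (0.00281) and without petal replicate 3 (0.0457). WRKY40 lay at 5.53 ± 0.19, ZAT10 at 4.99 ± 0.29 and CORI3 at 4.50 ± 0.25. Floral homeotic genes had 4 higher and 5 lower (median -0.21, mean -0.174, with the test upward; camera adjusted p = 0.412). AP1 lay at 5.87 ± 0.10, AG at -5.93 ± 0.37, PI at -4.43 ± 0.33 and AP3 at -0.50 ± 0.07. Flavonoid and floral volatile genes had 2 higher, 5 lower and 1 not passing (median -1.19; camera adjusted p = 0.257). MYB111 and F3H (AT3G51240) fell by 2.99 and 1.77, and MYB21 stood at 185 ± 32.1 CPM.

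Pollen tube genes had 12 lower and 11 not passing in sepals, and 9 lower adjusted over the list alone (median -2.90; camera adjusted p = 0.257, but 0.0247 with all A. thaliana libraries in the fit and 0.0431 with no low-count filter), TIP1;3 (AT4G01470) at -4.53 ± 1.90, ADF7 (AT4G25590) at -3.73 ± 1.35 and ACT4 (AT5G59370) at -3.45 ± 1.33. Their calls were lost without sepal replicate 1 (adjusted p = 0.0591, 0.0521 and 0.0685) or carpel replicate 1 (0.12, 0.147 and 0.163), that of ACT4 also without sepal replicate 2 (0.0525) or 3 (0.0514) or stamen replicate 2 (0.0521), and that of TIP1;3 without any 1 of 6 other libraries. Without petal replicate 3 TIP1;3, ADF7 and ACT4 lay at -3.42, -2.32 and -1.91. Sperm cell genes had 7 lower and 3 not passing (median -4.35; camera adjusted p = 0.257, but 0.0283 with all A. thaliana libraries in the fit and 0.0431 with no low-count filter). DAU2 (AT5G39650) lay at -6.37 ± 0.85 (-4.78 without petal replicate 3) and HAP2 had 2 counts, against 15.6 ± 1.78 CPM in stamens. Tapetum and exine genes had 5 higher, 6 lower and 3 not passing (median -0.38; camera adjusted p = 0.758). EXL6, GRP19 and GRP17 fell by 3.37, 2.61 and 2.24, lying at -4.65, -3.76 and -4.55 without sepal replicate 1, GRP17 losing its call without petal replicate 3 (adjusted p = 0.0847). Carpel and ovule genes had 3 higher, 10 lower and 4 not passing (median -1.46; camera adjusted p = 0.925); HEC3 and INO had 1 count each in sepals and IND (AT4G00120) 0. Outside carpels INO had only 3 counts, and HEC3 and IND stood at no more than 3.44 ± 0.732 and 0.303 ± 0.0166 CPM. Without petal replicate 2 neither INO nor IND was called (adjusted p = 1.0), nor was INO without stamen replicate 2 (1.0) or with all A. thaliana libraries in the fit (0.122). The highest genes were GRXC13 (AT2G47880, 9.43 ± 0.33), CHAT (AT3G03480, 9.36 ± 0.30), an acyltransferase of leaf volatile synthesis, and MES18 (AT5G58310, 8.90 ± 0.25). The lowest were AGO5 (AT2G27880, -7.80 ± 0.20), FOP1 (AT5G53390, -7.70 ± 0.37) and ASN1, at 0.880 ± 0.415 CPM in sepals and 2160 ± 273 in stamens. In sepals 19468 genes were called, 8741 higher and 10727 lower, and 9962 changed by at least 1. The split was 4945 to 15774 with spike-in counts, with a median of all genes at -1.0 (-0.35 with library totals, -0.21 with TMM).

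Between stage 16 and stage 18, A. thaliana seeds gained storage, oil body and desiccation transcripts and lost those of DNA replication and the early endosperm. The 12 seed storage and oil body genes all rose, from a sum of 0.422 ± 0.0441 to 84800 ± 2560 CPM (median 18.54, or 17.5 with the 6 members at 3 counts or fewer set to their bound; camera adjusted p = 2.16e-71, and adjusted p = 0.014 with an estimated correlation). The albumin genes SESA3 (AT4G27160, chromosome 4, 13611738 to 13613067; 7060 ± 242 CPM) and SESA5 (AT5G54740; 4160 ± 155 CPM) and the oleosin gene OLEO2 (AT5G40420; 3730 ± 135 CPM) had 0 counts at stage 16 and were at least 329000-fold, 194000-fold and 174000-fold higher. PHE1 (AT1G65330), an imprinted endosperm gene, had 32.8 ± 1.90 CPM at stage 16 and 0 counts at stage 18, at least 946-fold lower. The comparison asks what a maturing seed makes and what it ceases to make; SESA genes are close paralogs and may share reads.

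All 8 late embryogenesis and desiccation genes rose (median 11.3, or 11.0 with the 4 members at 3 counts or fewer set to their bound; camera adjusted p = 4.01e-07, adjusted p = 0.189 with an estimated correlation), PER1 (AT1G48130) by at least 102000-fold, M10 (AT2G41280) by 8570 times (1540 to 339000) and the dehydrin gene RAB18 (AT5G66400) by 12.44 ± 0.21. Of 9 seed maturation regulators 7 rose and 2 did not pass (median 6.37; camera adjusted p = 8.03e-09, and adjusted p = 0.014 with an estimated correlation): ABI3 (AT3G24650) stood at 663 ± 28.8 against 0.237 ± 0.0630 CPM, L1L (AT5G47670) rose by 9.03 ± 0.24, and the dormancy gene DOG1 (AT5G45830), with 3 counts at stage 16, was 21400 times higher (7310 to 104000). All 8 measured heat shock genes rose (median 2.90; camera adjusted p = 0.0124, adjusted p = 0.202 with an estimated correlation), HSP17.6A (AT5G12030) by 9.72 ± 0.88, HSP17.4 (AT3G46230) by 822 times (281 to 3990) and HSP70 by 5.81 ± 0.08.

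Cell division genes had 20 of 21 lower and 1 higher (median -5.05; camera adjusted p = 3.15e-15, adjusted p = 0.0964 with an estimated correlation), with PCNA1 at -7.30 ± 0.10, MCM7 at -6.68 ± 0.08 and CDKB1;1 (AT3G54180) at -6.31 ± 0.20. Endosperm genes had 6 lower and 2 higher (median -5.55; camera adjusted p = 0.00419, adjusted p = 0.187 with an estimated correlation), MINI3 (AT1G55600) at least 294-fold lower and FWA (AT4G25530) at -8.23 ± 0.14. Seed coat genes had 10 lower and 2 higher (median -1.50; camera adjusted p = 0.00419, adjusted p = 0.202 with an estimated correlation and 0.0713 with all A. thaliana libraries in the fit), the proanthocyanidin genes TT12 (AT3G59030) 25800 times lower (4630 to 1020000), BAN (AT1G61720) at -6.14 ± 0.14 and TT16 (AT5G23260) at -6.54 ± 0.10. Photosynthesis genes had 4 higher, 13 lower and 3 not passing and were not called as a list (median -0.61; camera adjusted p = 0.138, or 0.0376 with no low-count filter). RBCS2B, RBCS3B and RCA fell by 3.23, 3.06 and 2.47. The cellulase gene GH9B9 (AT2G44540), GASA12 (AT2G30810) and EXPA23 (AT5G39280), with 0 counts at stage 18, were at least 12000-fold, 6370-fold and 5220-fold lower. Of 22962 genes tested 20176 were called, 9694 higher and 10482 lower, and 11937 changed by at least 1. The split was 7237 to 13387 with library totals (median of all genes -0.51, against -0.07) and 4062 to 17626 with spike-in counts (-1.6), and no list count differed when adjusted over the list alone.

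In A. lyrata stamens, 22727 of 27549 genes differed between late stage 12 and stage 11, 11288 higher and 11439 lower, and 13806 changed by at least 1. AL4G23900 (scaffold 4) had 177 ± 16.6 CPM at late stage 12 and 0 counts at stage 11, at least 7470-fold higher. AL2G26940 (scaffold 2) had 27.8 ± 4.06 CPM at stage 11 and 1 count at late stage 12, 2240 times lower (402 to 88500). Of 3291 non-coding genes tested 1630 rose and 927 fell. The comparison asks how the transcriptome moves over the last stages of stamen development; the files pair these identifiers with no gene names, and the last age in the labels, 21 d for late stage 12 and 25 d for stage 11, does not follow the order of the stages. The split was 7048 to 16746 with library totals (median of all genes -0.71, against -0.018) and 7792 to 15326 with spike-in counts (-0.53).

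Mature A. thaliana pollen was set against the mean of root, hypocotyl, leaf, vegetative apex, inflorescence apex and carpel. The pectin methylesterase gene VGD1 (AT2G47040, chromosome 2, 19327853 to 19330264), which acts in pollen tube growth, stood at 40500 ± 4430 CPM in pollen and at most 13.9 ± 3.43 in any of the 6 organs (17.01 ± 0.20). PRK2A (AT2G07040, 18.81), CSLD4 (AT4G38190, 18.69) and MIOX5 (AT5G56640, 18.55) had the largest rises. Rises of single genes without SE, here and below, rest partly on organs at 0 CPM and so on the prior count. All 23 pollen tube genes rose (median 15.50; camera adjusted p = 6.45e-16, adjusted p = 0.0745 with an estimated correlation), as did all 10 pollen transcription factor genes (median 11.05; camera adjusted p = 1.7e-07, adjusted p = 0.0597 with an estimated correlation) and all 10 sperm cell genes (median 12.19; camera adjusted p = 2.54e-07, adjusted p = 0.0745 with an estimated correlation). The question is what separates the male gametophyte from the plant body.

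Named members of these lists were ANX2 (18.23), CPK17 (17.94) and PPME1 (17.50) of the pollen tube. Those of the transcription factors were AGL104 (AT1G22130, 16.88), MYB101 (AT2G32460, 15.89) and MYB97 (AT4G26930, 15.30). Those of the sperm cell were PCR11 (17.37), MGH3 (14.67 ± 0.07) and DAU2 (14.61). All 12 cytosolic ribosome genes fell (median -4.20; camera adjusted p = 1.19e-05, adjusted p = 0.277 with an estimated correlation), to 6.14 ± 0.870 CPM for PFL, while STV1 (AT3G53020) fell by 4.59 and RPS5A (AT3G11940) lay at -4.46 ± 0.08. Photosynthesis genes had 17 lower and 3 higher of 20 (median -2.64; camera adjusted p = 0.000125, adjusted p = 0.336 with an estimated correlation), GAPA (AT3G26650), PSAF (AT1G31330) and PSBO1 falling by 3.27, 3.26 and 3.24. Cell division genes had 11 higher and 10 lower (median 1.20, but -1.62 with library totals and -1.50 with spike-in counts; camera adjusted p = 0.124, or 0.0388 with RLE size factors and 0.0241 with nuclear protein-coding genes only): the Aurora kinase genes AUR2 and AUR1 (AT4G32830) rose to 1500 ± 61.7 and 1500 ± 51.9 CPM (5.97 ± 0.04 and 5.49 ± 0.03), and the cytokinesis gene KN (AT1G08560) fell by 5.50. Heat shock genes had 5 higher and 4 not passing of 9 (mean 2.60, but a median of -1.11 with library totals and -0.99 with spike-in counts; camera adjusted p = 0.135). HSP70 rose by 4.35 ± 0.07, and HSP18.2 rose as well but lay at -1.11 and -0.99 on those scales. Tapetum and exine genes had 5 higher, 2 lower and 8 not passing of 15, and 4 higher adjusted over the list alone (median -0.90, but 0.49 with RLE size factors and 1.85 with DESeq2; mean 0.487; camera adjusted p = 0.711). DRL1 (AT4G35420) and LAP6 (AT1G02050) fell by 3.13 (4.97 without pollen replicate 1) and 2.37. DTX9 (AT1G66760), BZS1 (AT4G39070) and SEN1 (AT4G35770) had 0 counts in pollen and at most 23.2 ± 2.30, 52.7 ± 0.439 and 63.1 ± 14.4 CPM in any organ.

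Over all 26770 A. thaliana genes tested 22508 were called in pollen, 9025 higher and 13483 lower, with a median of all genes at -1.6. The direction of the balance depended on the scale: 12517 higher and 9763 lower with DESeq2, 11118 and 9907 with RLE size factors, 5106 and 19017 with library totals (median -4.1) and 5188 and 18785 with spike-in counts (median -4.0). The same contrast called 26444 genes in A. lyrata (11443 higher, 15001 lower), 22382 in C. rubella (9081 and 13301), 24224 in E. salsugineum (9602 and 14622), 27396 in T. hassleriana (11051 and 16345), 28101 in M. truncatula (12324 and 15777) and 26487 in B. distachyon (10797 and 15690). Over the 7 species 39.6 to 43.9% of the called genes were higher in pollen, and 50.2 to 62.5% with DESeq2, 46.5 to 56.7% with RLE, at most 25.5% with library totals and 18.5 to 22.8% with spike-in counts. The highest protein-coding genes by the naming rule were AL1G56140 in A. lyrata (15.06), Carubv10025074m.g in C. rubella (19.53) and Thhalv10004453m.g in E. salsugineum (18.17). Likewise 104811242 was highest in T. hassleriana (16.24) and Medtr2g081220 in M. truncatula (16.82). Bradi1g55808 in B. distachyon, with 2 counts outside pollen, was 374000 times higher (103000 to 3090000). The lowest had 0 counts in pollen: AL4G30400 (1170 ± 89.6 CPM in leaf, at most 2.56 ± 0.434 in other organs), Carubv10020554m.g (849 ± 12.4 in hypocotyl), Thhalv10027441m.g (429 ± 17.5 in root), 104816803 (7.34 ± 0.620 or more in each organ), Medtr1g024005 (46.2 ± 1.98 in leaf) and Bradi1g07840 (501 ± 63.6 in spikelet meristem).

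Pollen expressed fewer protein-coding genes than the other organs in each of the 7 species, and its counts were concentrated in fewer genes. At a mean of at least 1 CPM, pollen held 10801 protein-coding genes on average over the species and the other organs 19103, a difference of -8301 ± 673 (SD over 7 species, lower in 7 of 7; exact sign-flip permutation p = 0.0156, adjusted p = 0.0195). The 100 most abundant genes took 34.5% of the counts in pollen and 11.3% in the other organs, 23.14 ± 3.09 percentage points more and higher in 7 of 7 species (exact p = 0.0156, adjusted p = 0.0195). The mean Spearman correlation across protein-coding genes with the other organs was 0.429 for pollen and 0.807 among those organs, a difference of -0.378 ± 0.0359 in 7 of 7 species (exact p = 0.0156, adjusted p = 0.0195). The smallest two-sided p that 7 species allow is 0.0156, and the species are related by descent. Non-coding genes gave 902 in pollen and 1190 in the other organs (-288 ± 469, lower in 6 of 7; exact p = 0.0781, adjusted p = 0.0781), a difference that did not pass. These comparisons ask whether pollen stands apart from other organs in the same way in each species.

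**Figure D3:**
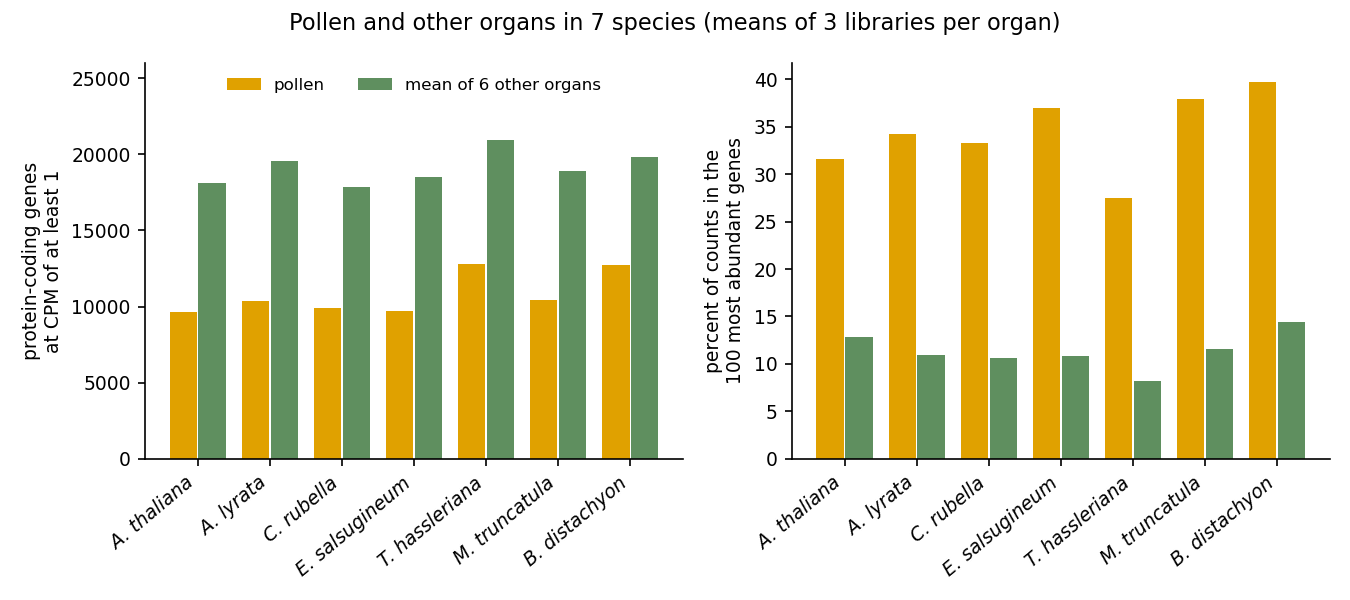
Protein-coding genes at a mean of at least 1 CPM (left) and percent of counts in the 100 most abundant genes (right) in pollen and in the mean of the 6 other organs, for 7 species; bars are values over 3 libraries per organ. In every species the pollen bar is lower on the left and higher on the right, from 27.5% in T. hassleriana to 39.7% in B. distachyon.

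Non-coding genes were more restricted to single organs than protein-coding genes. The median organ specificity tau, from 0 for even expression to 1 for a single organ over 8 organs, was 0.684 for non-coding and 0.372 for protein-coding genes on average, a difference of 0.312 ± 0.0661 in 7 of 7 species (exact sign-flip permutation p = 0.0156, adjusted p = 0.0195). In A. thaliana the medians were 0.709 over 1674 non-coding and 0.363 over 22441 protein-coding genes. Against protein-coding genes matched on their highest CPM the difference was -0.00162, above 0 in 3 of 7 species (exact p = 0.953), so at a matched level no difference was detected.

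**Figure D4:**
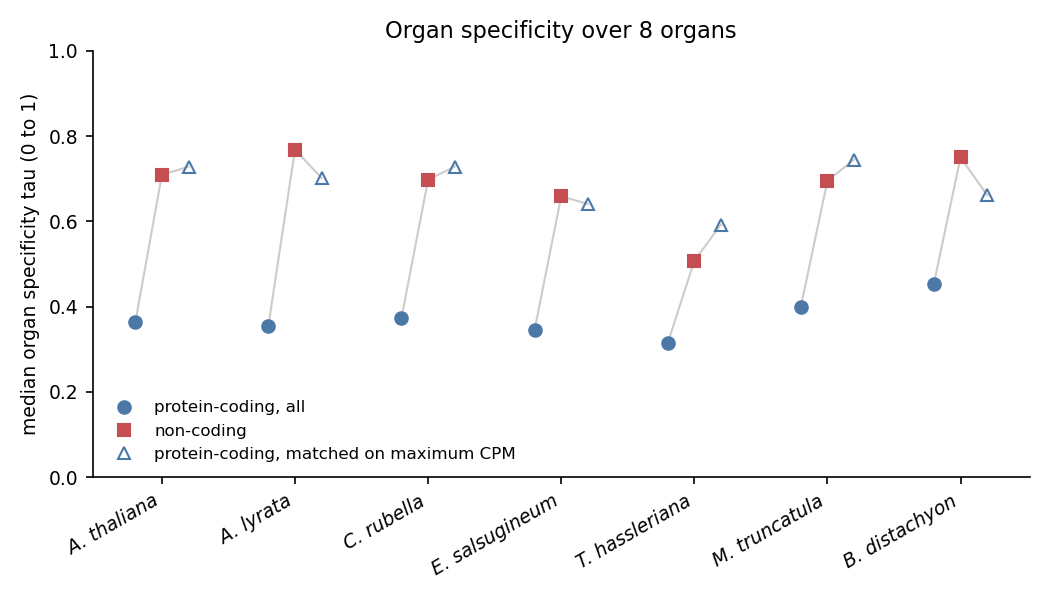
Median organ specificity tau over 8 organs for all protein-coding genes (circles), non-coding genes (squares) and protein-coding genes matched to the non-coding ones on maximum CPM (triangles) in 7 species; grey lines join the values of a species. The squares lie above the circles in all 7 species and above the triangles in 3 of 7.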

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

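The tests for carpel tissue, for younger stamens and on seed transcripts in cauline leaves were chosen after the result was seen. Values are CPM of library totals, and groups outside the comparisons were set against 18 root libraries.

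Pollen transcripts stood above the root libraries in stage 15 flowers. The pollen tube list summed to 11400 ± 1400 CPM in stage 15 stamens and 3050 ± 61.7 CPM in whole stage 15 flowers, against at most 132 CPM in a root library. The sperm cell list reached 281 ± 58.2 CPM in stage 15 stamens. Of 329 genes abundant in pollen and low in most other groups, the median share of the pollen level was 22.9% in stage 15 stamens, 5.04% in stage 15 flowers and 1.91% in stage 15 carpels.

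Among 7 species, T. hassleriana lay far from the others in non-coding genes detected, with -1283 in pollen against the other organs where the nearest species had -403.3, a gap of 0.614 of the range. Chance alone gives such a gap in about 1 in 20 groups. B. distachyon had 150.2 more in pollen while the other 6 species had fewer; the difference was not tested.

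Replicate 2 of the A. thaliana stage 15 stamens stood apart, with the cytosolic ribosome list at 1130 CPM against 571 and 592 CPM in replicates 1 and 3, the senescence list at 1610 against 2980 and 3020 CPM, and SAG12 at 71.1 against a mean of 466 CPM. The tables argue against a different amount of pollen, as the pollen tube list was at 10200 against 13000 and 11100 CPM (largest ratio 1.27). They argue against stage 12 stamens, as of 99 genes abundant there and low in replicates 1 and 3 only 41 were higher. Carpel tissue may have been in this library: 64 of 64 genes abundant in stage 15 carpels and low in replicates 1 and 3 were higher, at a median share of 12.4% of the carpel level (quartiles 10.5 and 15.8%), and the carpel and ovule list was at 117 against 40.1 and 45.2 CPM. Genes chosen likewise for other tissues were also nearly all higher, 108 of 108 for late stage 12 carpels (median share 8.82%), 156 of 156 for early stage 12 carpels (5.78%), 161 of 162 for the 21 d inflorescence apex (5.33%), 73 of 74 for stage 16 siliques (9.18%), 65 of 68 for the third internode (8.37%) and 20 of 22 for stage 15 flowers (25.1%), so these counts do not single out carpels. As a hypothesis carpel tissue leaves most of the senescence list open, and slightly younger stamens or changed expression within them were not tested.

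Seed storage transcripts were present in cauline leaves, where the storage and oil body list summed to 240 ± 21.1 CPM against at most 13.7 CPM in a root library, with SESA3 at 52.4, CRU3 at 42.0 and CRA1 at 31.8 CPM. Of 198 genes abundant in stage 18 seeds and low in most other groups, 158 lay within 2 times of a median share of 0.0540% of the seed level, so a uniform share of seed RNA or reads may be behind most of them. It is argued against as the whole source of the storage list, whose median share of 0.258% was 4.88 times the 0.0528% of the other seed genes, with 12 of 12 members above their upper quartile. Reads spread between libraries sequenced together cannot be told apart from seed RNA in the samples, since pollen genes too were present, at 0.0821% of the pollen level, the seed genes were also in mature pollen (0.0942%) and the 7 d vegetative apex (0.0628%), and the labels give no lane. Expression of storage genes in the leaf itself stays open as a hypothesis, and no biological explanation was tested.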

How the results depend on the processing

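The 28 d apex as reference, library totals or spike-in counts as the scale and the library total without its 100 most abundant genes were chosen after the data were seen. The counts of called genes in the 17 comparisons stayed within 1.5 times of the reported ones under every alternative run except an absolute log2 fold change of at least 1, which by its construction left 12332 of 19709 genes between root tip and maturation zone, 4515 of 15934 between the apices, 3366 of 15235 in clv1, 5302 of 14919 in senescing leaves, 12211 of 20823 in stamens, 11437 of 20565 in carpels, 6517 of 16892 in petals, 9962 of 19468 in sepals, 11937 of 20176 in seeds and 13806 of 22727 in A. lyrata stamens. Leave-one-out counts ran from 19433 to 19828 (root), 15163 to 15759 (apex), 14091 to 15182 (clv1), 14128 to 14651 (senescence), 20236 to 21119 (stamens), 20180 to 20742 (carpels), 15959 to 16905 (petals), 18812 to 19678 (sepals), 19806 to 20401 (seeds) and 22060 to 22890 (A. lyrata stamens), and in pollen from 21774 to 22706 (A. thaliana), 25934 to 26817 (A. lyrata), 21791 to 22615 (C. rubella), 23616 to 24494 (E. salsugineum), 26624 to 27566 (T. hassleriana), 26575 to 28963 (M. truncatula) and 25002 to 26998 (B. distachyon).

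Over all alternatives the named genes kept direction and side of the threshold in 6241 tests, lost the call in 60 and turned in 7. Leaving out 1 library moved 71 of the 313 fold changes by over 1.5 times, the most for SAG12 in senescing leaves and FEZ in the root tip, and turned 0. Those that turned were SEP3 (-0.78), CRC (-0.12), NGA3 (-0.23) and LHCB2.1 (-0.14) in clv1 against the 28 d apex, HSP101 in senescing leaves with spike-in counts (0.16), and HSP18.2 in pollen with library totals (-1.11) and spike-in counts (-0.99); the cause was not tested. Tests of lists stayed on their side of the threshold in 1405 cases, gained the call in 32 and lost it in 51, of which 35 were with an estimated correlation, where 7 of the 42 called of 80 remained.

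Replicate numbers were not taken to pair the libraries: 16 of 180 correlations of deviations between libraries of the same number were over 0.1, and in 0 of 17 comparisons were all of them. In 91 of the 180 cases the own number gave the highest correlation, where chance gives 1 in 3, and petals and sepals had all 3 over 0.1 (0.184, 0.123 and 0.176), a hint from the data and not from the labels. With the replicate block the count in senescing leaves went from 14919 to 14384, the largest relative move. Of the named genes none changed its call with the block; of the lists, the pollen tube list in carpels (camera adjusted p = 0.00159) and petals (0.0415) and the jasmonate list in sepals (0.0263) gained it and the floral homeotic list in petals lost it (0.164, against 0.00375).

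Fewer non-coding genes detected in pollen passed with a CPM of at least 2 (-206.5, exact p = 0.0469), without B. distachyon (-361, exact p = 0.0312) and with stamen and flower added (-318.6, exact p = 0.0469), against -288 and exact p = 0.0781; the cause was not tested. The tau difference turned to -0.001622 against protein-coding genes matched on maximum CPM, and with log2(CPM + 0.1) it was 1.227, where values below 0 take tau off its scale. The difference in protein-coding genes detected was -8308 after thinning and -7115 without the 100 most abundant genes in the totals, against -8301. A pseudocount cannot move a rank correlation, so Pearson correlation was run with it instead (-0.4897). Fewest simulated 1.5-fold changes were called in A. lyrata stamens (32.8%), at 28.97 M counts or more. B. distachyon pollen, the shallowest (8.02 to 14.43 M), had 64.2%, so depth does not set the low end.

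Other splits of the same libraries were fitted, and in each comparison 1 split, the real one, called as many genes. In the 10 splits of root, apex, clv1, senescence, seeds and A. lyrata stamens (14919 to 22727, highest other 0) a share under 0.05 is not possible. The share was under 0.05 in the 50 splits for stamens (20823, highest other 12146), carpels (20565, 9755), petals (16892, 481) and sepals (19468, 1559). In the 40 for pollen of each species (22382 to 28101, highest other 5429 to 6728) it was too. Other splits mix organs, so the real one was favoured and chance is not decided.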

Other observations

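The 28 d apex as reference was chosen after the result was seen, while the other tests in this part were set before the values they measure were seen. Of the 44 A. thaliana groups, 25 enter no comparison, and several gene lists were highest in them (CPM of library totals, mean ± SD of 3 libraries). The xylem and secondary wall list reached 7170 ± 814 CPM in the first internode, where 12 of 16 members peaked, against 1890 ± 198 CPM in stage 17a siliques, the next group. The tapetum and exine list reached 7870 ± 370 CPM in stage 10 to 11 flowers, the peak of 13 of 19 members, and 2720 ± 18.8 CPM in stage 12 flowers. In stage 15 flowers the senescence list was at 5210 ± 973 CPM in sepals and 3970 ± 855 CPM in petals, and the autophagy list at 1710 ± 200 CPM in petals. Endosperm genes were highest in stage 17a seeds (259 ± 9.21 CPM, the peak of 6 of 8).

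The clv1 libraries differed from the 21 d inflorescence apex in 15235 genes, of which 13083 (85.9%) were called in the same direction against the 28 d apex and 195 in the opposite one. The same clv1 libraries stand in both, and independent calls would share 2693 upward and 2613 downward; the overlap argues against an age between 21 and 28 d as the whole cause, while the label 21d+ leaves an older age open. A different share of older flowers in the dissected apex may contribute: the tapetum list had a median of 1.35 and the pollen tube list of 0.52, though most measured members of both were below 2 CPM and against the 28 d apex the medians were 2.35 and -2.11. A different time of day at harvest cannot be told apart, since the morning and evening clock genes had medians of 0.45 and 0.34, within the bound set against it, but members went both ways (PRR9 2.13, RVE1 1.93, LHY -0.51). A hypothesis from ASN1, a response to low sugar or darkness before harvest, was tested on 11 other low-energy genes: 11 of 11 were higher, with a median of 2.40 (2.20 against the 28 d apex), among them SEN1 (AT4G35770, 7.26 ± 0.19), BCAT2 (AT1G10070, 5.78 ± 0.38), DRM2 (AT2G33830, 3.73 ± 0.16) and TPS8 (AT1G70290, 3.08 ± 0.08), and their sum was 2000 ± 135 CPM against 336 CPM at 21 d and 378 CPM at 28 d, which is rank 4 of the 44 groups, after stage 15 petals (3160 CPM), stage 15 sepals (2630 CPM) and the first internode (2010 CPM), so other organs reach it too; the clv1 genotype itself stays open beside it, untested.

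Another hypothesis, that pollen holds a higher share of counts from LTR retrotransposons, was not borne out: the share was higher in 3 of 7 species, with a mean difference of -0.028 ± 0.11 percentage points (exact p = 0.531). By genes called on the TMM scale, more LTR retrotransposons were higher than lower in pollen in 6 of 7 species. They ran from 119 against 60 in A. thaliana to 614 against 180 in B. distachyon, with 271 against 282 in T. hassleriana. Non-coding genes leaned likewise in the same 6 species (1207 against 728 in A. thaliana).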
